A study of Mus musculus with 35 samples.

How the data were processed

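RNA was sequenced from 35 pieces of liver taken from 19 Balb/c mice. Per the labels' protocols, RNA was extracted with a column kit for small samples and libraries were made with a stranded kit that selects messenger RNA. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.7.3a, featureCounts and Subread 2.0.1, and the genome build was GRCm38. The authors deposited a table of whole-number read counts per gene from uniquely mapped reads and a second table of counts that includes multi-mapped reads. No normalization was applied to the deposited counts. Both tables hold 55487 gene rows, no row without a gene, and 0 columns that could not be tied to a sample. Whether the counting used the strand of the reads is not given in the sources used here, so overlapping genes on opposite strands may share counts. Gene symbols and positions were taken from a GRCm38 gene annotation, in which 55227 of the identifiers were found.

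Samples were grouped by area and time from the sample labels. HIGH is the highly irradiated area, LOW the area with no or very low dose in the same mouse, and control a mouse that was not irradiated. The replicate number in the labels ties HIGH and LOW to a mouse, so same-numbered samples of a time come from the same animal. As a check, the deviations of HIGH and LOW from their group means correlated across genes with r between -0.06 and 0.54, and the library of the same mouse was the best match in 11 of 13 mice. Titles and column names disagree on which piece of a control mouse came from which area at Day 1, Week 6 and Week 20. No pair of libraries had identical counts.

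The main test was edgeR (version 4.0.16, R 4.3.3) with quasi-likelihood fits and two-sided tests on the uniquely mapped counts. Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. HIGH was compared with LOW over the 26 libraries of the 13 mice with both areas. That fit held the mouse as a replicate block and a HIGH minus LOW difference for each of the 4 times, which left 9 residual degrees of freedom and a common biological coefficient of variation of 0.159. An F test asked whether the 4 differences were equal. LOW and HIGH were each compared with the 4 control mice with time as a term, after the pieces of a control mouse had been summed. The pieces of the 3 control mice with both areas were compared with the mouse as a replicate block.

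Gene lists were fixed before the data were examined, 36 in all, and 33 had at least 3 measured members. Each was tested with camera from limma (version 3.58.1) against all other tested genes, with a preset correlation between genes of 0.01, adjusted over lists and times. The same test was run with the correlation estimated from the data, and fry, which asks whether a list moves on balance, was run beside it. Named genes followed a rule that was also fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among genes that passed the test, had a mean of at least 1 CPM and moved the same way in every pair. It left out predicted genes and immunoglobulin or T cell receptor segments. It added up to 3 members of each list with the smallest p, 11 genes that were always reported, and the 8 genes with the smallest p for the difference between times. Genes outside the rule are named only as members of a counted set. A gene that the rule took for HIGH against control is not reported here.

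Expression levels are in CPM, read counts relative to the TMM-scaled library total, given as mean ± SD over mice. Log2 fold changes are given ± SE from the fit. Total counts per library ran from 26.6 to 65.7 M reads in the uniquely mapped table and from 31.7 to 85.4 M reads in the table with multi-mapped reads. Where a group had 0 reads of a gene, the fold was computed against a floor of 3 reads over the group. Intervals and floors pool the reads of a group and cover counting error only, not the spread between mice. They also take reads as independent, although reads amplified by PCR are not independent molecules.

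Alternatives fixed before the data were examined were a fit without the replicate block over all 28 irradiated libraries, limma-voom with a correlation within mice, DESeq2 (version 1.42.0), RLE scaling, no expression filter, multi-mapped counts, a fit of each time alone, and leaving out each mouse in turn. Alternatives chosen after seeing the data were a correction of each library for GC content and gene length, thinning of all libraries to 1 depth, a fit without the replicate block over the 26 paired libraries, and the use of control pieces of the matching area by column name. The GC and length correction was made in a first form that also recentred the libraries and in a second form that kept the TMM scale. The fits were tested on simulated counts with known changes, in 1 draw. For each comparison 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold. These are fewer than the genes called at each time, so the recovered shares need not hold for the real comparisons. At the size of the Day 1 comparison, edgeR recovered 26.9% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 93.9% of those changed 4-fold, out of 15211 genes tested. At the size of the Week 20 comparison the shares were 10.4%, 55.2% and 87.9%. False calls made up 3.7%, 1.7%, 4.3% and 1.9% of the edgeR calls in time order. For DESeq2 they made up 13.4%, 13.8%, 15.9% and 10.5%. Against control mice the edgeR shares were 4.3% (LOW) and 2.4% (HIGH), and those of DESeq2 11.4% and 16.6%. For the control areas they were 7.5% by edgeR and 7.7% by DESeq2. Markers of exocrine pancreas, skeletal muscle and fat cells were too few after the filter to be tested as lists.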

Results

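Messenger RNA was sequenced from liver of Balb/c mice, an inbred laboratory strain, after a single dose of 50 Gy to a small region where lobes of the liver meet. Each irradiated mouse gave a piece of the highly irradiated area (HIGH), which the labels describe as the area that later becomes fibrotic, and most gave a piece that had received little or no dose (LOW). Pieces were taken at Day 1, Day 6, Week 6 and Week 20. The 35 libraries came from 19 mice, of which 15 were irradiated and 4 were controls, with 1 control mouse at each time. There were 15 HIGH, 13 LOW and 7 control libraries, and 13 mice had both areas (4 at Day 1 and 3 at each later time). Total uniquely mapped counts ran from 56.3 to 65.7 M reads in HIGH at Day 1 and from 27.9 to 40.8 M reads in LOW at Day 1. At the later times HIGH and LOW libraries held 26.6 to 49.3 M reads. The control libraries held 26.6 to 47.4 M reads. By the lane tag in the column names, all HIGH libraries of Day 1 were run in lane 5 and all LOW libraries of Day 1 in lane 4. At Day 6 LOW was in lane 3 and HIGH in lanes 3 and 4, at Week 6 LOW was in lane 2 and HIGH in lanes 2 and 3, and all libraries of Week 20 were in lane 1.

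Each HIGH library was compared with the LOW library of the same mouse to find the genes that differed with local irradiation at each time. Of 15655 genes tested by edgeR, 4508 differed at Day 1 (2453 higher and 2055 lower in HIGH), 1185 at Day 6 (507 higher, 678 lower), 431 at Week 6 (285 higher, 146 lower) and 595 at Week 20 (418 higher, 177 lower). Changes of at least 2-fold were mostly rises, with 723 genes higher and 213 lower at Day 1, and 269 higher and 19 lower at Week 20. The share of called genes that were higher was 54.4% at Day 1, 42.8% at Day 6, 66.1% at Week 6 and 70.3% at Week 20. Across genes, which are not independent replicates, Spearman's rho of the fold change with GC content was -0.43 at Day 1, 0.39 at Day 6, 0.04 at Week 6 and -0.22 at Week 20. With gene length it was 0.26, -0.08, -0.15 and 0.32 in time order. A correction for GC content and gene length, chosen after seeing the data, was made in a form that also recentred the libraries and in a form that kept the TMM scale. The recentred form called 1507 genes higher and 2304 lower at Day 1, 471 and 888 at Day 6, 437 and 930 at Week 6, and 598 and 1464 at Week 20. It moved the median of all genes at Week 20 by -0.118. At TMM scale the correction called 3410 genes (57.7% higher), 1367 (34.9%), 883 (61.5%) and 916 (65.0%) in time order.

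**Figure D1:**
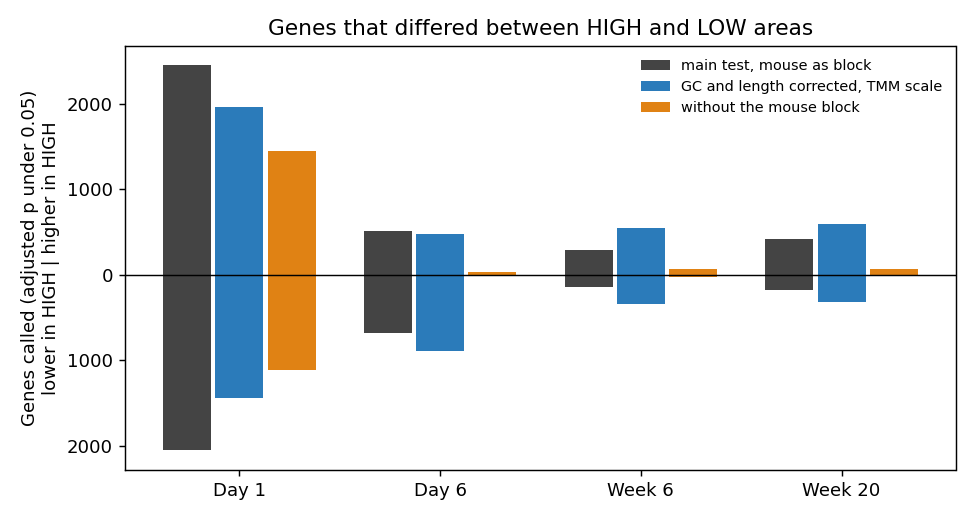
Number of genes called higher (upward bars) or lower (downward bars) in HIGH than in LOW at each time, by the paired edgeR test, after the GC and length correction at TMM scale, and without the replicate block over all 28 irradiated libraries. The paired test called 4508 genes at Day 1, 1185 at Day 6, 431 at Week 6 and 595 at Week 20, and the fit without the block called 2570, 40, 91 and 70.

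At Day 1, p53 target genes rose together in HIGH. Of 22 measured, 20 rose and 0 fell, and 21 rose when adjusted over the list alone, with a median log2 fold change of 1.80. The list test gave an adjusted p of 5.15e-39, and adjusted p = 0.0506 with an estimated correlation. Mdm2, which encodes the ubiquitin ligase that degrades p53, stood at 139.9 ± 32.3 CPM in HIGH and 23.2 ± 2.85 CPM in LOW (mean ± SD, n = 4), a log2 fold change of 2.58 ± 0.18 (SE). Cdkn1a, a cyclin-dependent kinase inhibitor (chromosome 17, 29090976 to 29100727, GRCm38), stood at 248 ± 43.7 CPM in HIGH and 79.7 ± 36.4 CPM in LOW, and at 13.3 and 17.7 CPM in the pieces of the control mouse. Its log2 fold change was 1.79 ± 0.37 (adjusted p = 0.00373). Eda2r rose by 4.08 ± 0.47 on the log2 scale, Tnfrsf10b, a death receptor, by 3.62 ± 0.27, Ccng1 by 3.12 ± 0.25, and Phlda3, a repressor of Akt signalling, by 4.29 ± 0.30. Among the genes that the naming rule took from outside the list, which leave out predicted genes, the largest rises were those of Sec14l5 (7.41 ± 0.48, chromosome 16, 5147109 to 5187271), the glutamate receptor subunit Gria3 (5.58 ± 0.44), the cytokine Lif (5.39 ± 0.44) and Inka2 (5.14 ± 0.31), followed by Mybl1 (4.61 ± 0.40), Ddit4l (4.42 ± 0.30) and Ckap2 (4.29 ± 0.69). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.81 ± 0.31 and the stress cytokine Gdf15 by 1.65 ± 0.24.

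Immune cell genes fell in HIGH at Day 1. Of 8 measured MHC class II genes, 6 fell and 0 rose, and 7 fell when adjusted over the list alone (median -1.13, adjusted p = 3.26e-11, and adjusted p = 0.183 with an estimated correlation). Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), fell by 1.61 ± 0.14, H2-Aa by 1.48 ± 0.15 and H2-Ab1 by 1.27 ± 0.13 on the log2 scale. Of 10 Kupffer cell markers 7 fell, the same number as when adjusted over the list alone (adjusted p = 1.35e-06, and adjusted p = 0.307 with an estimated correlation), among them the complement genes C1qa (-1.32), C1qb (-1.28) and C1qc (-1.27). Of 15 monocyte and macrophage markers 8 fell, and 8 fell and 1 rose when adjusted over the list alone (adjusted p = 0.000327, and adjusted p = 0.352 with an estimated correlation), with Fcgr1 at -1.48 ± 0.22 and the receptor gene Csf1r at -1.11. Of 14 T and NK cell markers 5 fell, also when adjusted over the list alone (adjusted p = 0.00311, and adjusted p = 0.307 with an estimated correlation), with Trbc2 at -1.53 and Cd3g at -1.29. Among 12 sinusoidal endothelial markers 7 fell and 1 rose (8 and 1 when adjusted over the list alone, adjusted p = 0.000224, and adjusted p = 0.387 with an estimated correlation). Dnase1l3 fell by 1.15, Oit3 by 0.87, and Lyve1, a hyaluronan receptor, rose by 0.55.

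Genes of hepatocyte secretion and metabolism were also among those that fell at Day 1. Hamp, which encodes the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), fell by 1.79 ± 0.23 from 1327 ± 381 CPM in LOW (n = 4), and its near copy Hamp2, which may share reads with it, fell by 1.97 ± 0.25. Serpina6, the corticosteroid-binding globulin, fell by 1.71 ± 0.22, the zinc transporter gene Slc39a5 by 1.55 ± 0.27, Gal3st1 by 1.56 ± 0.31, and G0s2, a lipase inhibitor, by 1.65 ± 0.35. Of 14 sterol synthesis genes 6 fell (8 when adjusted over the list alone, adjusted p = 0.000224, and adjusted p = 0.492 with an estimated correlation), with Fdps at -1.45, Sqle at -1.35 and Cyp51 at -1.09. Of 27 nuclear-encoded respiratory chain genes 8 fell (9 when adjusted over the list alone, adjusted p = 0.000849, and adjusted p = 0.648 with an estimated correlation). Of 7 red blood cell markers 4 fell, also when adjusted over the list alone (adjusted p = 0.00311, and adjusted p = 0.387 with an estimated correlation). Of 17 hepatocyte genes 6 fell and 2 rose (7 and 3 when adjusted over the list alone, adjusted p = 0.0206, and adjusted p = 0.315 with an estimated correlation), with Apoa1 at -1.02 and the transthyretin gene Ttr at -0.82. Cyp2e1, a pericentral cytochrome, fell by 0.64 ± 0.21 (adjusted p = 0.0334). Among genes that did not pass the test, Col1a1 stood at -0.26, Col3a1 at -0.38, Timp1 at 0.21, Mki67 at -0.59, Glul at -0.25 and Acta2 at 0.84 (adjusted p = 0.113).

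The pieces of the Day 1 control mouse also differed, without irradiation. Over 3850 of the genes called at Day 1, the piece named as the high area in the column names differed from the other in the same direction for 84.3%, with a median ratio of 0.597 to the HIGH minus LOW change. Sample titles name these pieces the other way round, and in that orientation the values were 15.7% and -0.597. The pieces of the Week 6 and Week 20 control mice, by column name, went in the same direction for 47.3% and 21.7% of these genes. Across genes, Spearman's rho of the control piece difference with GC content was -0.69 at Day 1, 0.27 at Week 6 and 0.47 at Week 20, by column name. By column name, the differences between the pieces of the Day 1 control mouse had a median of -0.38 for MHC class II genes, -0.31 for Kupffer cell markers, -0.37 for sinusoidal endothelial markers, -0.28 for sterol synthesis genes, -0.23 for respiratory chain genes, -0.86 for red blood cell markers and 0.11 for p53 targets. For monocyte and macrophage markers the median was -0.01 and for hepatocyte genes -0.12. Without the replicate block, and with the mice that gave HIGH only, 2570 genes passed the Day 1 test, and Cdkn1a, Cyp7a1, Cyp2e1 and G0s2 did not. Leaving out pair 3 left 1613 genes and leaving out pair 4 left 2038. The call of Cyp2e1 was lost whichever pair was left out, and that of Trbc2 was lost without pair 3.

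At Day 6, 15 of 22 p53 targets were still higher in HIGH and Perp, a junction gene, was lower (median 1.01, 15 and 1 when adjusted over the list alone). The list test gave an adjusted p of 6.97e-14, and adjusted p = 0.227 with an estimated correlation. Lif rose by 6.34 ± 0.65, Sec14l5 by 5.27, Rec114 by 5.16, Inka2 by 4.36, Phlda3 by 4.10 ± 0.38 and Gria3 by 3.82 on the log2 scale (n = 3 pairs). Gdf15 rose by 1.18 ± 0.27, Mdm2 by 0.99 ± 0.21 and Cdkn1a by 1.57 ± 0.46 (adjusted p = 0.0496). Pericentral hepatocyte genes were lower, 4 of 14 measured and 6 when adjusted over the list alone (median -0.49, adjusted p = 0.000117, and adjusted p = 0.387 with an estimated correlation). Glul, the glutamine synthetase gene of hepatocytes around the central vein (chromosome 1, 153899944 to 153909723), fell by 0.86 ± 0.14 (adjusted p = 0.00582), from 936 ± 118 CPM in LOW (n = 3), and the control mouse had 870 CPM. The 3 paired HIGH libraries had 444 to 567 CPM of Glul, while HIGH replicate 4, which has no LOW partner and is not in the paired test, had 1200 CPM of Glul and 10390 CPM of Cyp2e1. In the paired test Cyp2e1 fell by 0.88 ± 0.25, the Wnt target gene Lgr5 by 0.84 and Tbx3 by 0.57.

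Genes of fatty acid oxidation fell in HIGH at Day 6, 6 of 19 measured and 14 when adjusted over the list alone (median -0.55, adjusted p = 5.57e-09, and adjusted p = 0.351 with an estimated correlation). Hadhb fell by 0.72 ± 0.16 and Etfdh by 0.82 ± 0.18. After the GC and length correction, in the recentred form, they stood at -0.40 ± 0.22 and -0.66 ± 0.23 and neither passed (adjusted p = 0.265 and 0.0873). Cyp4a14, a fatty acid hydroxylase with near copies that may share reads (chromosome 4, 115486200 to 115496142), fell by 2.86 ± 0.69 (adjusted p = 0.026). Of 12 fatty acid synthesis genes 2 rose and 0 fell (3 rose when adjusted over the list alone, adjusted p = 3.39e-05, and adjusted p = 0.387 with an estimated correlation). These were Mlxipl (0.96), a carbohydrate-responsive transcription factor, and Pnpla3 (2.12 ± 0.58), which stood at 1.81 ± 0.59 after that correction (adjusted p = 0.0656). Of 7 mitochondrially encoded genes 4 fell (5 when adjusted over the list alone, adjusted p = 0.000104, and adjusted p = 0.387 with an estimated correlation), with mt-Nd6 at -0.97 and mt-Nd1 at -0.95, and the ribosomal RNA gene mt-Rnr1 fell by 1.59. These transcripts differed by a median of 1.36 between the pieces of the Day 1 control mouse. Among sinusoidal endothelial markers 3 rose (5 when adjusted over the list alone, adjusted p = 0.000178, and adjusted p = 0.387 with an estimated correlation), with Lyve1 at 1.56 ± 0.17. Of 10 vascular endothelial markers 3 rose, also when adjusted over the list alone, led by Cd34 at 1.73 (adjusted p = 0.0212, and adjusted p = 0.403 with an estimated correlation). Falls in Rad51b (-2.06), Unc79 (-1.70), Nek2 (-1.63), Lgalsl (-1.50) and Ugt1a9 (-1.49) were among the largest falls taken by the naming rule. Acta2 at 1.45 (adjusted p = 0.0692), Timp1 at 0.60, Col1a1 at 0.45, Col3a1 at 0.26 and Mki67 at -1.20 did not pass.

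At Day 6, 40 genes were called without the replicate block over all libraries, and Glul, Lyve1, Mdm2 and Cdkn1a were not among them. With the paired mice alone the fit without the block called 239, which included Glul, Lyve1 and Mdm2 and not Cdkn1a. The count was 346 by limma-voom and 0 by edgeR in a fit of Day 6 alone (1238 at an unadjusted p under 0.05), against 1856 by DESeq2 in the full fit. Leaving out pair 1 gave 2018 genes, pair 2 gave 537 and pair 3 gave 676. The call of Cdkn1a was lost without pair 1 or pair 2. Mdm2, Lgr5, Tbx3, Ugt1a9, mt-Nd1 and mt-Nd6 lost the call without pair 2 or pair 3, Gdf15 and Rad51b without pair 2, and Cyp2e1, Hadhb, Etfdh and Unc79 without pair 3. Only pair 3 had both libraries in 1 lane, which is too few for a value within a lane. Over 1041 of the genes called at Day 6, the pieces of the Day 1 control mouse, by column name, differed in the same direction for 14.3%, those of Week 6 for 74.7% and those of Week 20 for 75.7%. By sample title these values were 85.7%, 25.3% and 24.3%.

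At Week 6, MHC class II genes were higher in HIGH, the opposite direction to Day 1. Of 8 measured, 6 rose and all 8 rose when adjusted over the list alone (median 0.98, adjusted p = 9.14e-13, and adjusted p = 0.183 with an estimated correlation). H2-Eb1 rose by 1.02 ± 0.17, H2-Aa by 1.00 ± 0.17 and H2-DMb1 by 1.35 on the log2 scale (n = 3 pairs). H2-Aa stood at 88.6 ± 68.5 CPM over the 4 HIGH libraries, of which replicate 3 had 190.9 CPM. Of 22 p53 targets 12 were higher (18 when adjusted over the list alone, median 0.97, adjusted p = 6.84e-20, and adjusted p = 0.183 with an estimated correlation). Phlda3 rose by 3.99 ± 0.39, Eda2r by 3.49 ± 0.61 and Cdkn1a by 1.69 ± 0.43 (adjusted p = 0.0493), while Mdm2 at 0.62 (adjusted p = 0.118) did not pass. Apln, the ligand of the receptor encoded by Aplnr (chromosome X, 48025146 to 48034853), had 1 read in the 3 LOW libraries and 404 reads in the paired HIGH libraries, a ratio of 303 with an interval from 54.1 to 12010. Aplnr rose by 2.81, and the endothelial genes Esm1, Cd34 and Lyve1 by 3.31 ± 0.60, 1.99 and 1.98. Lyve1 is on the list of sinusoidal endothelial markers, which did not rise with it and had a median of -0.28 at Week 6. Of 10 vascular endothelial markers 4 rose (6 when adjusted over the list alone, adjusted p = 0.000104, and adjusted p = 0.3 with an estimated correlation). Marco, a scavenger receptor of macrophages (chromosome 1, 120474538 to 120505024), fell by 3.65 ± 0.50. Cd163, the receptor for haemoglobin bound to haptoglobin, fell by 2.29 ± 0.25 from 22.4 ± 1.79 CPM in LOW to 4.69 CPM in HIGH. Marco is on the list of Kupffer cell markers, which did not fall with it and had a median of 0.23 at Week 6.

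Genes on the cytokine, macrophage and matrix lists were also higher at Week 6. The pieces of the unirradiated Week 6 mouse differed, by column name, by a median of -0.94 over cytokines, -0.72 over monocyte and macrophage markers, -0.07 over matrix genes, -0.25 over MHC class II genes and -0.31 over vascular endothelial markers. By sample title these differences have the opposite sign, the direction of the changes in HIGH. Acta2 levels, given below for the control pieces, go with the column names instead. Of 16 cytokines and chemokines 3 rose (8 when adjusted over the list alone, adjusted p = 1.66e-05, and adjusted p = 0.227 with an estimated correlation), namely Ccl4 (2.78), Ccl5 (1.40) and Ccl2 (1.30). Of 15 monocyte and macrophage markers 3 rose (5 when adjusted over the list alone, adjusted p = 2.13e-05, and adjusted p = 0.307 with an estimated correlation), namely Gpnmb (1.97), Trem2 (1.60) and Ctss (0.76). Of 15 genes linked to senescence 5 rose (7 when adjusted over the list alone, adjusted p = 0.000224, and adjusted p = 0.227 with an estimated correlation), including the matrix metalloproteinases Mmp3 (3.34), Mmp12 (1.75) and Mmp13 (1.47). Of 29 matrix genes 5 rose (8 when adjusted over the list alone, adjusted p = 4.77e-06, and adjusted p = 0.43 with an estimated correlation). They included the proteoglycan gene Lum (1.25 ± 0.17), Mfap4 (1.68), Loxl2 (1.06) and Timp1, a metalloproteinase inhibitor (2.04 ± 0.39, adjusted p = 0.0143). Col1a1 at 1.00 (adjusted p = 0.156), Col3a1 at 0.84 (adjusted p = 0.12) and Acta2 at 1.14 (adjusted p = 0.193) did not pass. Sterol synthesis genes rose, 4 of 14 and 10 when adjusted over the list alone (adjusted p = 2.87e-09, and adjusted p = 0.307 with an estimated correlation), with Mvd at 1.76 and Sqle at 1.60. Pericentral genes fell, 2 of 14 and 6 when adjusted over the list alone (adjusted p = 1.69e-05, and adjusted p = 0.353 with an estimated correlation). Elovl3 (-2.62), Cyp2c54 (-1.78), which has near copies, Nnmt (-1.55) and Dio1, a thyroid hormone deiodinase (-1.38), were among the largest falls taken by the naming rule. Sult2a7, a sulfotransferase with near copies, rose by 4.29 ± 0.91.

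Without the replicate block 91 genes passed at Week 6, and leaving out pair 1, 3 or 4 left 70, 22 and 149. Pairs 3 and 4, the ones with both libraries in 1 lane, gave the value of 70 on their own with the other times in the fit. The calls of Phlda3, Apln, Marco, Cd163 and Cd34 held whichever pair was left out, those of Cdkn1a and Loxl2 were lost whichever pair was left out, and those of H2-Eb1, H2-DMb1, Timp1 and Lum were lost without pair 3.

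At Week 20, genes of the extracellular matrix rose in HIGH. Of 29 measured, 15 rose and 0 fell, and 25 rose when adjusted over the list alone, with a median log2 fold change of 0.87. The list test gave an adjusted p of 3.26e-21, and adjusted p = 0.227 with an estimated correlation. Col3a1, a fibrillar collagen gene (chromosome 1, 45311538 to 45349706), stood at 101.1 ± 47.7 CPM in HIGH and 36.5 ± 6.54 CPM in LOW (mean ± SD, n = 3), with 29.1 and 40.1 CPM in the control pieces. Its log2 fold change was 1.35 ± 0.28 (adjusted p = 0.0221), and that of Col1a1 was 1.25 ± 0.36 (adjusted p = 0.0595, not called). Timp1 (chromosome X, 20870166 to 20874735) stood at 3.46 ± 0.116 CPM in HIGH and 1.08 ± 0.274 CPM in LOW, a rise of 1.64 ± 0.30, and Lum and Fbln2 rose by 1.59 ± 0.17 and 1.45 ± 0.23. Of 15 stellate cell and myofibroblast markers 3 rose (4 when adjusted over the list alone, adjusted p = 0.000103, and adjusted p = 0.307 with an estimated correlation), namely Cnn1 (3.41), Vim (0.96) and Pdgfra (0.74). Acta2 stood at 1.63 ± 0.45 (adjusted p = 0.054). The pieces of the Week 20 control mouse, in the orientation of the column names, differed by a median of 0.46 over these markers and of 0.21 over the matrix genes. Acta2 stood at 1.17 CPM in one of these pieces and 12.8 CPM in the other, and Cnn1 at 0 and 2.57 CPM. Of 14 genes of TGF-beta signalling 2 rose, Ltbp2 (1.40) and Tgfbr2 (0.79), and 7 rose when adjusted over the list alone (adjusted p = 0.000103, and adjusted p = 0.23 with an estimated correlation).

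Monocyte and macrophage markers and MHC class II genes were higher in HIGH at Week 20. Of 15 monocyte and macrophage markers 7 rose (9 when adjusted over the list alone, median 0.85, adjusted p = 1.12e-11, and adjusted p = 0.183 with an estimated correlation), with Lyz2, the lysozyme gene, at 1.32 ± 0.20, Ctss at 1.16 and Gpnmb at 2.30 ± 0.37. Marco, on the list of Kupffer cell markers, stood at 0.0639 CPM in HIGH and 3.2 ± 0.442 CPM in LOW, a log2 fold change of -5.77 ± 0.65. Of the 10 members of that list 1 fell, also when adjusted over the list alone (median -0.14, adjusted p = 0.0446, and adjusted p = 0.658 with an estimated correlation). The call of that list was lost after the GC and length correction (adjusted p of 0.302 and 0.243 in its forms). MHC class II genes were higher, 4 of 8 and 7 when adjusted over the list alone (adjusted p = 1.69e-05, and adjusted p = 0.307 with an estimated correlation), with H2-Aa at 82.8 ± 15.4 CPM in HIGH and 46.4 ± 1.33 CPM in LOW. Of 22 p53 targets 9 rose (12 when adjusted over the list alone, median 0.77, adjusted p = 2.86e-07, and adjusted p = 0.307 with an estimated correlation), with Eda2r at 3.19 ± 0.64 and Cdkn1a at 1.71 ± 0.44 (adjusted p = 0.0439). Cdkn1a stood at 43.2 ± 22.9 CPM in HIGH and 16.1 ± 13.8 CPM in LOW, but at 50.3 and 51.5 CPM in the pieces of the control mouse. Nuclear-encoded respiratory chain genes were lower, 7 of 27 and 25 when adjusted over the list alone (median -0.45, adjusted p = 3.37e-15, and adjusted p = 0.307 with an estimated correlation). Uqcrfs1 fell by 0.58, Atp5o by 0.67 and Cox5a by 1.08 on the log2 scale. By column name, the pieces of the Week 20 control mouse differed by a median of 0.22 over respiratory chain genes, -0.36 over monocyte and macrophage markers and 0.09 over MHC class II genes, and by sample title these have the opposite sign. Periportal genes fell, 2 of 12 and 6 when adjusted over the list alone (adjusted p = 5.8e-05, and adjusted p = 0.307 with an estimated correlation), namely the glutaminase gene Gls2 (-0.88) and Ass1 of the urea cycle (-0.59).

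Among the other genes that the naming rule took at Week 20 was Dmbt1, a secreted scavenger protein gene (chromosome 7, 131032053 to 131121630). It had 0 reads in the 3 LOW libraries and 751 reads in HIGH, at least 235-fold higher against the floor of 3 reads over the group, while the pieces of the control mouse stood at 0 and 17.6 CPM. Sult2a7 (3.67 ± 0.90), the imprinted non-coding RNA H19 (2.88 ± 0.44), Gria3 (2.88 ± 0.54), Pls1 (2.76) and Smpd3, a neutral sphingomyelinase (2.49), also rose. The largest falls taken by the rule after Marco were those of Scand1 (-1.66), Serpina1c (-1.30), Tmem238 (-1.26), Kcnk10 (-1.26) and the globin genes Hba-a2 (-1.24), Hbb-bt (-1.18) and Hbb-bs (-1.18), of which Serpina1c and the globins have near copies. By edgeR, leaving out pair 1 left 0 genes called at Week 20 (1946 at an unadjusted p under 0.05), leaving out pair 2 left 9 and leaving out pair 4 left 273. By the index numbers in the column names at Week 20, LOW of pairs 2 and 4 carried 3 and 2 and HIGH of these pairs 7 and 6, while LOW of pair 1 carried 8 and HIGH of pair 1 carried 4. Whether the areas of pair 1 were exchanged is left open by this order. The labels were kept. HIGH of pair 1 had more Eda2r than LOW (4.76 and 0.765 CPM) and more Phlda3 (9.16 and 2.72 CPM). It also had more Cdkn1a (62.5 and 30.2 CPM), Gdf15 (27.7 and 18.8 CPM) and Mdm2 (27.4 and 19.2 CPM). Pairs 2 and 4 had the same direction for all of these p53 targets, which argues against an exchange in pair 1. Among the genes named here for Week 20, Lum, Dmbt1, Marco and Tmem238 kept the call without pair 2. Without the replicate block 70 genes passed, and a fit of Week 20 alone called 3542. Over 462 of the genes called at Week 20, the pieces of the Week 20 control mouse differed in the same direction for 27.7% by column name and 72.3% by sample title, and those of the Week 6 control mouse for 24.03% and 75.97%.

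**Figure D2:**
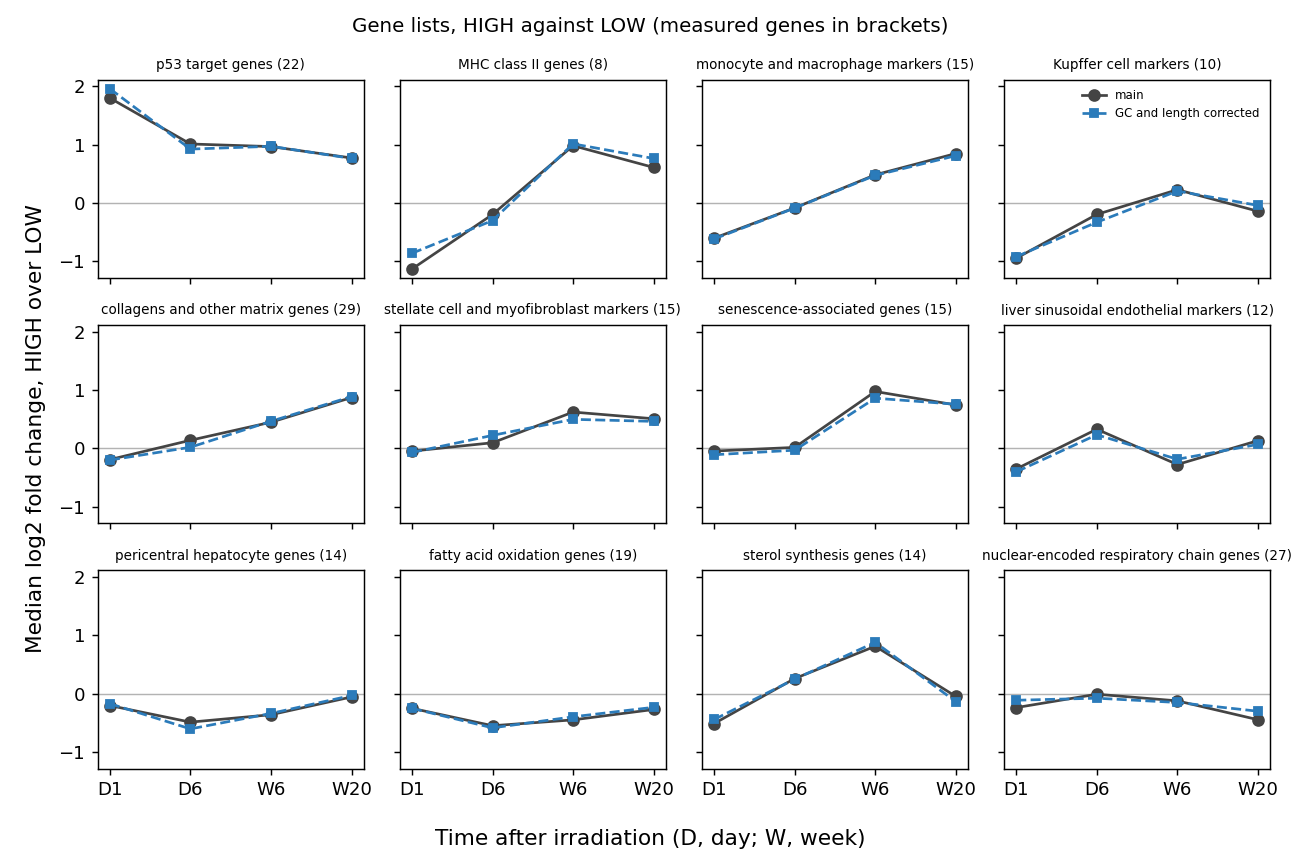
Median log2 fold change, HIGH against LOW, of 12 gene lists at the 4 times, from the paired fit and after the GC and length correction at TMM scale. The median of MHC class II genes was -1.13 at Day 1 and 0.98 at Week 6, that of matrix genes was -0.19 at Day 1 and 0.87 at Week 20, and that of p53 targets went from 1.80 at Day 1 to 0.77 at Week 20.

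The differences between HIGH and LOW were tested for equality over the 4 times, and 2478 genes passed. The MHC class II genes H2-Aa, Cd74 and H2-Ab1 had the smallest p (adjusted p = 0.000324 each), followed by H2-Eb1. H2-Aa stood at -1.48 ± 0.15 at Day 1, -0.25 ± 0.17 at Day 6, 1.00 ± 0.17 at Week 6 and 0.79 ± 0.16 at Week 20. The change of the list from Day 1 to Week 6 (2.30) and to Week 20 (1.98) passed with an estimated correlation too (adjusted p = 0.0317 each). Matrix genes rose by a median of 1.27 from Day 1 to Week 20 relative to LOW (adjusted p = 1.1e-23, and adjusted p = 0.164 with an estimated correlation), and p53 targets changed by -1.18 (adjusted p = 3.7e-19, and adjusted p = 0.158 with an estimated correlation). Cotl1, Rhoc, the phospholipid transfer protein gene Pltp and Hmcn2 completed the smallest p (adjusted p = 0.00162 each). Hmcn2 went from 3.55 ± 0.24 at Day 1 to 0.38 ± 0.27 at Week 20, and Pltp from -0.78 ± 0.17 at Day 1 to 1.72 ± 0.20 at Week 6. The difference over times also passed for Mdm2 (adjusted p = 0.00212), Col3a1 (0.0289) and Glul (0.0477), and not for Cdkn1a (0.988). After the GC and length correction 1731 genes passed in the recentred form and 1754 at TMM scale. Of the 2478 main calls, these forms kept 1325 and 1353. Without the replicate block 252 genes passed. Leaving out pair 1, 2, 3 or 4 of Day 1 left 1361, 1053, 609 and 805 genes, and pair 1 or 3 of Week 6 left 1306 and 1493. Leaving out pair 1, 2 or 4 of Week 20 left 1124, 1322 and 1430, and pair 3 of Day 6 gave 4784.

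Across the 4 times, 23 genes were higher in HIGH at every time and 0 were lower at every time, where independent lists would share 0.0386 genes. Of these, 7 were among the 22 p53 targets, namely Ccng1, Cdkn1a, Eda2r, Phlda3, Plk2, Tnfrsf10b and Zmat3 (odds ratio 443, Fisher's exact test, two-sided, p = 9.03e-16). The endothelial markers Cd34 and Lyve1 and the genes Gria3, Inka2, Lif, Ddit4l, Mybl1 and Sult2a7 were also among them. Lyve1 stood at 0.55 ± 0.15, 1.56 ± 0.17, 1.98 ± 0.17 and 1.01 ± 0.19 in time order. After the GC and length correction 21 of the 23 remained in either form. The numbers higher and lower at all 4 times were then 36 and 19 in the recentred form and 38 and 2 at TMM scale. Of the 23, 1 remained without the replicate block, which called 1 gene at all 4 times. None remained without pair 1 or pair 2 of Week 20, 5 without pair 3 of Week 6, 8 without pair 1 of Week 6, 10 without pair 4 of Week 20, 14 without pair 4 of Week 6, and 15 without pair 1, 2 or 4 of Day 1. Genes higher at both Week 6 and Week 20 numbered 77, where independent lists would share 7.61. This number was 0 and 5 without pair 1 and pair 2 of Week 20, 34 without its pair 4, 25, 10 and 50 without pair 1, 3 and 4 of Week 6, and 169 and 157 without pair 2 and pair 3 of Day 6. Genes higher at both Day 1 and Day 6 numbered 242, against 79.4. Genes lower at both Day 1 and Day 6 numbered 70, against 89.0 (odds ratio 0.754, Fisher's exact test, two-sided, adjusted p = 0.0295). Those lower at both Day 1 and Week 6 numbered 38, against 19.2, and those lower at both Day 1 and Week 20 numbered 85, against 23.2 (odds ratios 2.35 and 6.33, the same test, adjusted p = 5.66e-05 and 3.21e-29). Fisher's test takes genes as independent, which they are not, so these p-values do not measure the spread over mice. Overlaps between pairs of times were not counted after the GC and length correction. Spearman's rho of the fold change with GC content was -0.43 at Day 1, 0.39 at Day 6 and -0.22 at Week 20.

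**Figure D3:**
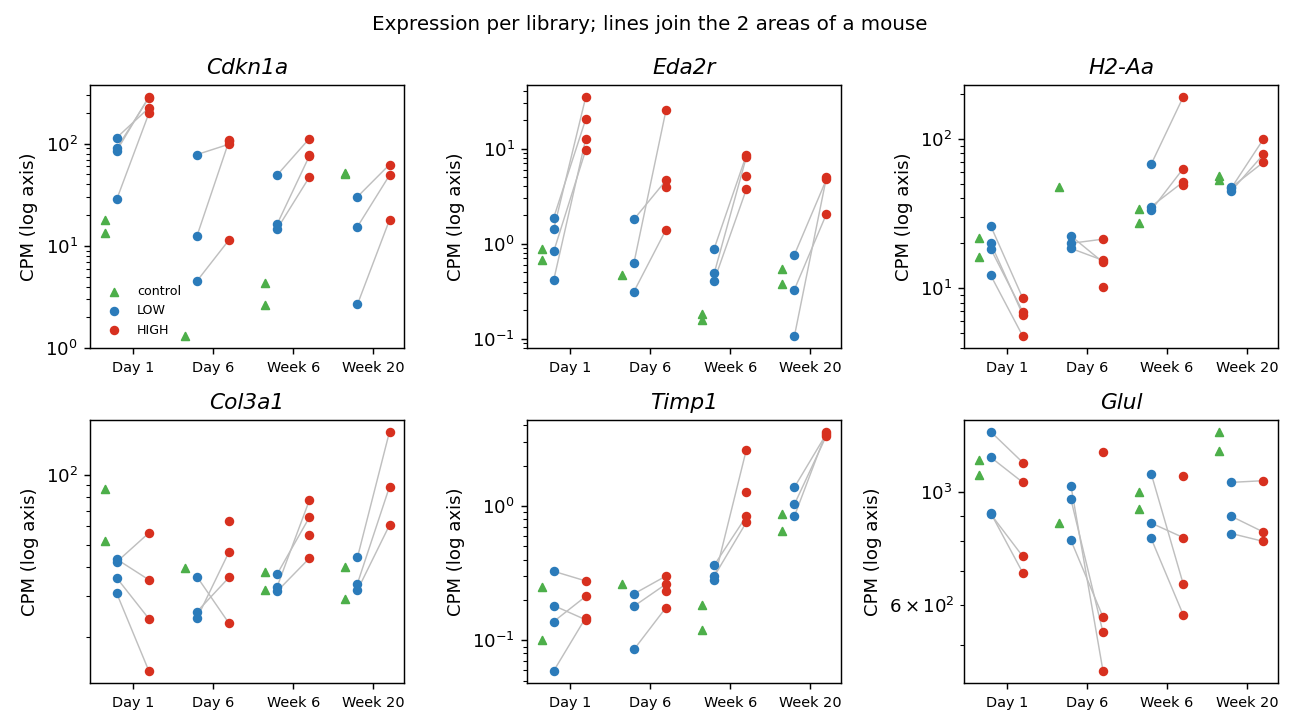
CPM per library, on a log axis, of Cdkn1a, Eda2r, H2-Aa, Col3a1, Timp1 and Glul at each time, with control pieces as triangles, LOW in blue, HIGH in red, and lines that join the areas of a mouse. Cdkn1a averaged 248 CPM in HIGH and 79.7 CPM in LOW at Day 1, and Col3a1 averaged 101.1 CPM in HIGH and 36.5 CPM in LOW at Week 20.

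LOW was compared with the control mice to see whether the spared area differed from unirradiated liver. Of 14671 genes, 3 were lower in LOW and 0 higher (993 at an unadjusted p under 0.05, and 42 called by DESeq2). The smooth muscle myosin gene Myh11 fell by 1.86 ± 0.29 (adjusted p = 0.0438), the matrix gene Dpt by 1.01 ± 0.16 (adjusted p = 0.0438) and the troponin gene Tnnt2 by 2.36 on the log2 scale (n = 13 LOW and 4 control mice). All 3 also differed between the pieces of control mice, and with control pieces of the matching area by column name 0 genes passed (959 at an unadjusted p under 0.05), with Dpt at 0.10 and Myh11 at -0.07. Of 22 p53 targets 0 were called, also when adjusted over the list alone (median 0.17, adjusted p = 0.00419, and adjusted p = 0.625 with an estimated correlation). Mdm2 stood at 0.01 and Cdkn1a at 1.29 ± 1.02 (adjusted p = 0.783). As a list, circadian clock genes were lower (median -0.56, 0 of 15 called, 6 lower and 2 higher when adjusted over the list alone, adjusted p = 4.34e-06), and this held with an estimated correlation (adjusted p = 0.0211). NRF2 antioxidant genes were higher as a list, with 0 called and 5 when adjusted over the list alone (median 0.26, adjusted p = 1.83e-05, and adjusted p = 0.196 with an estimated correlation). With 1 control mouse per time, leaving out the control of Day 1, Week 6 or Week 20, LOW replicate 1 of Day 1, or any LOW library of Week 6 left 0 genes. Leaving out LOW replicate 3 of Day 1 or replicate 2 of Week 20 left 1, LOW replicate 3 of Day 6 gave 7, and the control of Day 6 gave 17.

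HIGH was compared with the control mice in the same way, and 59 of 15613 genes differed (51 higher, 8 lower, n = 15 HIGH and 4 control mice). p53 targets led, with 8 of 22 higher and 18 when adjusted over the list alone (median 1.16, adjusted p = 4.71e-39), and the list also passed with an estimated correlation (adjusted p = 0.0111). Phlda3 rose by 4.30 ± 0.67 (adjusted p = 0.00848), Eda2r by 4.20 ± 0.71, Tnfrsf10b by 3.57 ± 0.54 and Zmat3, an RNA-binding protein gene, by 1.54 ± 0.22. Lif rose by 5.07 ± 1.09, Inka2 by 4.88 ± 0.76, Gria3 by 4.24, Ddit4l by 3.93 and Sult2a7 by 3.55. Dio1 fell by 1.63 ± 0.32, Cd163 by 1.29 ± 0.23, Gbp11 by 1.21, Kcnk5 by 1.03 and Lipg by 0.92. Cdkn1a at 2.80 ± 0.90 (adjusted p = 0.276), Gdf15 at 1.39 (0.15), Mdm2 at 1.08 (0.169) and Timp1 at 1.45 (0.233) did not pass. No matrix gene was called, although the list was higher (median 0.19, adjusted p = 0.048, and adjusted p = 0.841 with an estimated correlation). Without the control mouse of Day 6 edgeR called 0 genes (1146 at an unadjusted p under 0.05), without that of Day 1 it called 10 and without that of Week 20 it called 38. With control pieces of the matching area from 3 mice it called 0 (1211 at an unadjusted p under 0.05). Leaving out HIGH replicate 2, 3 or 4 of Day 1 left 35, 37 and 34 genes, replicate 1 or 3 of Week 6 left 34 and 36, and replicate 2 of Week 20 left 37. A fit without the time term called 6 and limma-voom called 103.

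The pieces of the 3 control mice with both areas were compared to see how areas differ without irradiation. Of 13894 genes, 9 differed. Acta2, smooth muscle actin, stood at 16.1, 16.7 and 12.8 CPM in one piece and at 0.97, 1.82 and 1.17 CPM in the other, a log2 difference of 3.56 ± 0.22 (adjusted p = 0.00182). Cnn1, the calponin of smooth muscle, differed by 6.34 ± 0.64, the actin gene Actg2 by 5.89 ± 0.50, Tnnt2 by 4.66 ± 0.37, Pdlim3 by 3.56 ± 0.39, Myh11 by 2.82 ± 0.28, Myl9 by 2.16 ± 0.21, Tpm2 by 2.10 ± 0.21 and Dpt by 1.98 ± 0.23. Of 10 Kupffer cell markers 0 were called and 6 when adjusted over the list alone, and these were higher in the piece with less Acta2 (median 0.50, adjusted p = 7.85e-15, and adjusted p = 0.323 with an estimated correlation). The piece rich in Acta2 was the one titled as the low area and named as the high area in the column names. The labels alone therefore leave open the area it came from. The Day 6 control piece, the low area by title and column name alike, had 0.57 CPM of Acta2. The 13 LOW libraries of irradiated mice had 0.99 to 3.06 CPM. Both go with the column names. The Day 6 value rests on 1 piece, and the LOW values count only if irradiation did not lower Acta2 there. Leaving out the Day 1, Week 6 or Week 20 mouse gave 238, 35 and 43 genes, with 2 mice in the fit.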

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

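The thinning to 1 depth, the GC and length correction and the tests of the lane and of the pieces of the Day 1 control mouse were chosen after the data or the results were seen. Of 88 tests for a library far from the other 3 of its group, 9 passed Dixon's critical value, where chance gives about 1 in 20. At Day 6, HIGH replicate 1 had 11.45 CPM of Cdkn1a (the others 99.0 to 108 CPM), HIGH replicate 4 had 1200 CPM of Glul (444 to 567 CPM), and HIGH replicate 3 had 25.4 CPM of Eda2r (1.41 to 4.63 CPM) and 20.4% of its reads in the top 10 genes. At Week 6, HIGH replicate 3 had 190.9 CPM of H2-Aa and 342 CPM of Cd74, and HIGH replicate 1 had 0.0123% of its reads in globin genes. At Day 1, LOW replicate 1 had 1.82 CPM of Marco and LOW replicate 4 had 19119 genes detected.

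Among differences between times, H2-Aa, Cd74 and H2-Ab1 (adjusted p = 0.000324 each) were lower in HIGH in 4 of 4 pairs at Day 1, and higher in HIGH in 3 of 3 pairs at Week 20. H2-Eb1 (0.000414), Cotl1, Pltp, Hmcn2 and Rhoc (0.00162 each), Mdm2 (0.00212), Col3a1 (0.0289) and Glul (0.0477) also differed between times by edgeR. As a list, MHC class II genes differed between Week 6 and Day 1 and between Week 20 and Day 1 with an estimated correlation (adjusted p = 0.0317 each).

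The number of genes called at Day 1, 4508, was weighed against technical explanations. Depth alone is argued against, since 86.1% of the calls were kept in direction when all libraries were thinned to 1 total, although HIGH was sequenced more deeply. GC content and length bias stays open as a part of the pattern, since 57.6% of the calls were kept after the correction at TMM scale and 62.6% in the recentred form, as does the lane, since 0 pairs of Day 1 had both libraries in 1 lane. A difference between pieces that needs no irradiation also stays open, since the pieces of the Day 1 control mouse gave a median ratio of 0.597 to the change over the called genes by column name but -0.597 by sample title, and over all 3 control mice the ratio for an effect of the liver area was 0.0977 by column name, with mice from -0.301 to 0.572. Both pieces of the Day 1 control mouse were in lane 4, so their difference arose within 1 lane. The piece named high in the columns held 47.4 M reads and the other 26.6 M, with 4.03% and 1.69% of reads in mitochondrial genes. The difference between the Day 1 control pieces had a Spearman's rho of -0.69 with GC content by column name. It could therefore not be told apart from GC bias. The rise of p53 targets is argued against as part of that difference between pieces, with a ratio of 0.0437 and an upper quartile of 0.212 by column name, and a biological effect of the dose on the other genes could not be separated from what stays open.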

How the results depend on the processing

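The GC and length correction, the thinning, the control pieces of the matching area and the fit of paired mice without the block were chosen after seeing the data. Without the replicate block, over all 28 irradiated libraries, the counts of called genes were 2570 at Day 1, 40 at Day 6, 91 at Week 6, 70 at Week 20 and 252 for the difference between times. Without the replicate block over the paired mice alone they were 2549, 239, 101, 90 and 301, and the voom fit gave 346 at Day 6 and 103 for HIGH against control. DESeq2 gave 1856 at Day 6, 840 at Week 6, 1310 at Week 20, 4165 for the difference between times, 42 for LOW and 213 for HIGH against control, and 24 for the control areas. Without the expression filter edgeR gave 2148 at Day 6, 1113 at Week 6, 1768 at Week 20, 4671 for the difference between times, 45, 148 and 70 for LOW, HIGH and the control areas. A fit of 1 time alone gave 0 at Day 6 and 3542 at Week 20, where fewer samples set the spread. The GC and length correction gave 1367 genes at Week 6 and 2062 at Week 20 in the recentred form and 883 and 916 at TMM scale. HIGH against control gave 6 without the time term, and control pieces of the matching area gave 0 for LOW and 0 for HIGH. With an estimated correlation 0, 0, 0 and 0 lists were called in time order where the preset correlation called 15, 10, 18 and 16, and fry called 6 at Day 6. Leaving out 1 mouse gave 1613 to 3335 genes at Day 1, 537 to 2018 at Day 6, 22 to 149 at Week 6, 0 to 273 at Week 20, 609 to 4784 for the difference between times, 0 to 17 for LOW, 0 to 86 for HIGH and 35 to 238 for the control areas. Apart from the changes that fewer samples or more genes tested bring by construction, the cause was not tested. All other counts stayed within 1.5 times, and 1 call of a named gene reversed its direction, that of Dpt in LOW, which stood at 0.10 with control pieces of the matching area. A like count can hold other genes. The 3 genes that limma-voom called for LOW against control included 0 of the main ones. The GC and length correction kept 812 of the 1185 calls of Day 6 in the recentred form and 819 at TMM scale. Among named genes, the fit without the block ended the call for 32 of 122 genes at Day 1, 43 of 121 at Day 6, 33 of 123 at Week 6 and 41 of 123 at Week 20, and over the paired mice alone 27, 26, 29 and 38. The correction at TMM scale ended 16, 10, 0 and 3 calls, and DESeq2 ended 1, 0, 1 and 3 and added 4, 21, 19 and 17. Simulated 2-fold changes were recovered in 55.2% of genes at the depth and size of Week 20, which limits what the later times can show. Fewer genes were changed in that simulation than were called, so the share is only a guide. In the simulation of Day 6, 13.8% of the DESeq2 calls were false, against 1.7% by edgeR.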

Other observations

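The tests of the hepatocyte share, of the smooth muscle genes and of p53 targets in LOW and the GC and length correction of respiratory chain genes were chosen after the data or the results were seen, and the other groupings of samples were set out before. Among circadian clock genes at Day 6, Ciart (2.41 ± 0.63), Per3 (2.30 ± 0.53), Dbp (2.27 ± 0.65), Tef (1.04 ± 0.26) and Per2 (0.99 ± 0.18) rose in HIGH and Clock fell by 1.29 ± 0.30, so that 5 of 15 rose and 1 fell, and 7 and 4 when adjusted over the list alone (n = 3 pairs). The list as a whole did not pass (adjusted p = 0.062), and Per3 and Clock lost the call without pair 2 or pair 3. In LOW against control mice, Ciart stood at -1.86 and Nr1d2 at -0.67, neither of which passed as a single gene. The time of day at which pieces were taken is not given in the sources used here.

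Other gene groups also differed. Red blood cell markers were lower in HIGH at Week 20, 4 of 7, also when adjusted over the list alone (median -1.18, adjusted p = 0.000941, and adjusted p = 0.315 with an estimated correlation). Neutrophil markers were higher at Week 6, with 1 of 8 called, Mpo at 2.81, and 5 when adjusted over the list alone (median 1.48, adjusted p = 5.8e-05, and adjusted p = 0.307 with an estimated correlation). Over 4 neutrophil markers, control pieces of Week 6 differed by a median of -1.07 by column name, with the opposite sign by sample title. Cholangiocyte markers were higher at Week 20, with 1 of 10 called, Krt19 at 1.51, and 2 when adjusted over the list alone (median 0.53, adjusted p = 0.0223, and adjusted p = 0.48 with an estimated correlation), but they also differed by a median of 0.87 between the pieces of the Week 20 control mouse. Fatty acid oxidation genes were lower at Week 6 with 0 of 19 called and 2 when adjusted over the list alone (median -0.45, adjusted p = 2.25e-07, and adjusted p = 0.387 with an estimated correlation). Cell cycle genes were lower at Day 1, 3 of 23 and 1 when adjusted over the list alone, among them Aurka at -0.98 (adjusted p = 0.00342, and adjusted p = 0.648 with an estimated correlation).

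The fall of respiratory chain genes at Week 20 (median -0.45) was weighed against a lower share of hepatocytes and against GC content. Pericentral hepatocyte genes had a median of -0.06 (two-sided permutation test over genes against the respiratory chain genes, p = 1e-05). That p is the smallest that the permutations can give. General hepatocyte genes had a median of -0.31 (the same permutation test, p = 0.00608). The test shuffles genes, which are not independent, so these p-values do not measure the spread over mice. These medians were taken before the GC and length correction. The general hepatocyte median therefore does not decide on an equal loss of all hepatocytes as the whole cause. The pericentral median goes against such a loss but, uncorrected too, does not settle the question. Periportal genes had a median of -0.38 (permutation test, p = 0.389), so a lower share of hepatocytes outside the pericentral zone stays open. GC content and length stay open as a part of it, because the median was -0.30 after the correction at TMM scale and -0.40 in the recentred form, with the list still called (adjusted p = 1.37e-12 and 5.5e-13). A biological change with the dose was not tested apart from these. Nor was it tested apart from the difference of 0.22 between control pieces of Week 20 by column name. That difference has the direction of the fall only by sample title, and Acta2 in LOW, given below, goes with the column names.

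The smooth muscle genes that differed between control pieces may mark a difference between areas of the liver that needs no irradiation. The mean of these genes was higher in HIGH than in LOW in 12 of the 13 irradiated mice, replicate 3 of Day 1 being the exception. This goes with that hypothesis if the column names of the control pieces are right and against it if the sample titles are right. The Day 6 control piece, the low area by both, had 0.57 CPM of Acta2 and 0 CPM of Cnn1. Acta2 stood at 0.99 to 3.06 CPM in the 13 LOW libraries and at 1.00 to 12.4 CPM in the 15 HIGH libraries. Control pieces named low in the columns had 0.97, 1.82 and 1.17 CPM, and those named high 16.1, 16.7 and 12.8 CPM. These values go with the column names and argue against the sample titles, unless irradiation lowered Acta2 in LOW. On that reading the 12 of 13 mice go with an area difference. More stellate cells in one area are argued against, since 8 stellate cell genes without a contractile role gave a ratio of -0.0235 to the difference of the smooth muscle genes. Whether irradiation added to the difference at any time stays open.

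A hypothesis that LOW at Day 1 shared part of the p53 response, raised by Cdkn1a at 79.7 CPM in LOW against 13.3 and 17.7 CPM in the control pieces, was tested on the other 21 targets. Of these, 17 were higher in LOW than in the control mouse, but their median difference was 0.146 of the HIGH minus LOW difference, and 1 control mouse leaves the question open.

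Other groupings of the same samples were counted. Exchanging HIGH and LOW within pairs gave 0 genes in each of the other groupings, against the real 4508 at Day 1 (1 of 8 groupings as large), 1185 at Day 6, 431 at Week 6 and 595 at Week 20 (1 of 4 each), and 0 against 9 for the control areas (1 of 4), and these groupings are too few for a share under 0.05. For the difference between times, 1 of 60 assignments of pairs to times gave as many as 2478 genes and the highest other gave 0. A chance assignment of pairs to times can be excluded there, but not a bias of GC content or lane that differed between times. With another mouse of each time in place of the control, 3 of 100 groupings gave at least the 3 genes of LOW against control (highest other 6), and 2 of 100 gave at least the 59 genes of HIGH against control, so both shares are under 0.05. The true controls are mostly sums of 2 pieces and the exchanged mice are single pieces, so these counts do not exclude chance for an effect of irradiation, and with control pieces of the matching area 0 genes passed in either comparison. The highest other of HIGH against control gave 169 genes with 2 true control mice among its controls, and whether a structure of the samples beyond the groups underlies this was not tested.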
